A study of Mus musculus with 22 samples.

How the data were processed

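Gene expression was measured by poly(A) RNA sequencing (paired-end Illumina reads, TruSeq libraries) in 22 mouse libraries from C57Bl/6 mammary cells. The deposited values are FPKM (fragments scaled to transcript length and to the size of the library), per the names of the 2 deposited tables. Reads were checked with FastQC, trimmed with Trim Galore, aligned with TopHat to the mouse genome build mm9 and quantified with Cufflinks, per the submitters' processing notes, which state no versions. The gene annotation, any filter and the scaling between libraries are not given in the sources used here, except that the name of the larger table points to the normalisation program of the Cufflinks suite. No read counts were analysed here.

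The first table held 16 libraries, of which 6 were cultures and 10 were allografts, with 23993 gene symbols. The second table held 6 libraries, namely 2 primary cancers and 4 cultures grown from them, with 23735 entries for 23490 symbols. The 407 entries that shared a symbol with another entry (162 symbols) were summed. The tables were normalised separately, so every test was made within 1 table. Of the values above 0 in the second table, 51.5% carried more than 6 digits, and 97.2% of those ended in 5, the form that the mean of a pair of 6-digit values takes; the first table held no such values. There, 6 of 3508 genes with at least 10 FPKM in every library of the first table were listed at 0 in at least 1 library, and 3 of them in all 6. A 0 there may therefore be a missing estimate, and genes with such values are described as listed at 0.

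Each library was placed in a group by its title. Among 135 pairs of libraries within a table none was identical, and the highest correlation across genes was 0.982. The depth of sequencing cannot be read from FPKM. The steps between low values of a gene put what a single fragment was worth in the other libraries at 0.966 to 4.44 times its worth in CRC allograft 10C, and at 0.536 to 1.04 times that of primary cancer 1 in the second table, but at most 8.15% of genes fell in the most frequent bin, so these ratios are rough. A larger worth means fewer fragments, so that CRC culture 3, at 4.44, had the coarsest values of the first table.

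Differential expression was tested with limma (lmFit and eBayes with a trend) on log2(FPKM + 1), over genes with a mean of at least 1 FPKM in the libraries of the fit. Genes were called at a Benjamini-Hochberg adjusted p under 0.05. Fold changes are on the log2(FPKM + 1) scale, which understates the change of genes with low values; a stated fold is 2 to the power of that difference. Medium was tested in the 6 cultures and in the 10 allografts with genotype in the model. The allografts were compared with the cultures over all 16 libraries with genotype and medium in the model, and the medium by state interaction was added to test whether the medium effect differed between allografts and cultures. Genotypes were compared among the 6 CRC allografts with Brca1 alleles, and among the cultures and the allografts with medium in the model. In the second table the 3 groups entered 1 model. Residual degrees of freedom ranged from 2 to 11.

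The 30 gene lists (23 of pathways and epithelial states, 7 of other cell types) were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists of a comparison, for lists with at least 5 tested genes; camera with an estimated correlation and fry were run beside it. The choices of tests, lists, alternatives and the rule for named genes were made before the data were examined. That rule took 6 marker genes of the study (Brca1, Trp53, Esr1, Pgr, Erbb2 and Cyp19a1); in each comparison the 6 called genes with the largest increase and the 6 with the largest decrease, with a mean of at least 5 FPKM in the higher group and the same direction in every pair or no overlap between groups; and up to 3 called members of each called list, or 2 of a list that was not called. Where fewer than 12 genes were called, the rule took the 4 genes with the smallest p in each direction. Only some of these are given, as values. Genes outside the rule are named as chosen after their values were seen.

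In the second table libraries with the same number come from the same cancer, per their titles, so the numbers pair the libraries. The deviations from the group means of same-numbered libraries correlated across genes at −0.0555 between cancers and CRC cultures, −0.113 between cancers and EpiC cultures and 0.242 between the kinds of culture. The main model had no block, and the fit with the cancer as a block is given beside the results it changed. Other alternatives were a pseudocount of 0.1, no filter, a filter at 5 FPKM, rescaling by median ratios, leaving out each library in turn, models without genotype or with Brca1het libraries alone, and counting CRC allografts 10B and 10C as 1 sample. Fits without genes of chromosome 4, without small RNA genes and without genes listed at 0, and lists without EpiC culture 3, without the CRC culture of cancer 2 or with the block, were added after seeing the data.

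The test was tried on simulated values with each gene's own mean and residual spread. In these, 200 genes were changed by 2-, 4-, 8- or 32-fold, 50 genes each. The changed genes were drawn only from those with an average level, on the scale of the fit, of at least 5 FPKM. The real tests also covered genes below that level, for which the shares called were not tried. Of the genes changed 4-fold, the medium test called 46% in the 6 cultures and 72% in the 10 allografts, the allograft against culture test called 92%, and the interaction called 48%. The genotype tests called 84% in CRC allografts, 66% for CYP19A1 in allografts, and 46% (Brca1hom) and 48% (CYP19A1) in cultures. In the second table no gene changed 4-fold was called; of the genes changed 32-fold, 0% were called for CRC cultures against cancers, 26% for EpiC cultures against cancers and 34% between the kinds of culture. Among the genes left unchanged, at most 9 were called in any comparison. The simulated spread was drawn independently for each gene and library. The simulation therefore cannot show false calls that come from a structure shared by genes or libraries.

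Chromosomes and neighbouring genes came from a RefSeq gene table of assembly GRCm38.p6, matched by symbol for 22502 of the symbols of the first table (93.8%) and 21919 of the second (93.3%). It was used only for chromosome names and gene order, since the files were made on mm9, and no positions are given. Analyses used R 4.3.3, limma 3.58.1, Python 3.11.15 and matplotlib 3.10.9.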

Results

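The study set side by side a pair of ways to grow mouse mammary cells: a medium optimised for mammary epithelium, called EpiC in the labels, and conditional reprogramming (CRC), in which epithelial cells are usually grown with irradiated fibroblast feeders. The cells came from nulliparous female mice that carried 1 mutant Trp53 allele. They also carried an inducible CYP19A1 (aromatase) transgene (here CYP19A1), 1 conditional Brca1 allele (Brca1het) or 2 (Brca1hom), with Cre under the MMTV promoter. There was 1 CRC culture and 1 EpiC culture of each of the 3 genotypes, numbered 1 for CYP19A1, 2 for Brca1het and 3 for Brca1hom. Cells of these kinds were grown as allografts in mammary glands of nude (Foxn1 mutant) hosts. Of the 7 CRC allografts, 6C was CYP19A1, 10B, 10C and 11C were Brca1het, and 1, 2 and 12 were Brca1hom. Of the 3 EpiC allografts, 7B was CYP19A1 and 4C and 5A were Brca1het. In addition, 2 primary cancers of the Brca1het genotype were each sequenced with a CRC and an EpiC culture. Their titles share a number, so both cancers may come from 1 animal. The labels do not say whether libraries of a group came from separate animals or cultures, so p-values measure the spread between these samples, which may be technical.

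FPKM sums ran from 466400 to 825200 in the 16 cultures and allografts, and 11164 to 11784 genes reached 1 FPKM in each. Among the cancers and their cultures the sums lay between 607500 and 710500, except for 1616000 in the CRC culture of cancer 2, where the 10 most abundant genes took 18.1% of the sum. Several epithelial genes were near 0 in EpiC culture 3: the keratin Krt8 stood at 0.275 FPKM, Krt18 at 0.684, Epcam at 0.208 and Cdh1 (E-cadherin) at 0.106. In the other 5 cultures these genes stood at 205 to 725, 238 to 943, 253 to 454 and 100 to 199 FPKM.

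Brca1, the conditional gene of these mice, lay between 2.02 and 5.61 FPKM in the cultures and allografts. It stood at 2.47 ± 0.118 FPKM (SD, n = 2) in Brca1hom cultures and 3.75 ± 0.21 (n = 2) in Brca1het cultures, with a limma adjusted p of 0.959. Its gene-level value cannot show the loss of the conditional part of the gene. In CRC allografts Brca1 stood at 3.93 ± 1.16 FPKM for Brca1hom and 3.31 ± 0.173 for Brca1het (n = 3 each, limma adjusted p = 0.795). In the cultures and allografts Trp53 ranged from 2.09 FPKM in EpiC culture 2 to 32.6 in CRC allograft 6C. Mouse Cyp19a1 never exceeded 0.014 FPKM, and the human transgene was not analysed here. The oestrogen receptor gene Esr1 stayed at or below 3.08 FPKM, while the progesterone receptor gene Pgr reached 6.64 FPKM in EpiC culture 3 and at most 0.407 in the other cultures and allografts. Erbb2 lay between 1.86 and 17.7 FPKM in the cultures and allografts.

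Most squamous and several basal genes were higher in CRC cultures, and most collagen and mesenchymal genes were higher in EpiC cultures. Krt5, a keratin of basal epithelium, stood at 4985 ± 506 FPKM in CRC and 1.85 ± 0.735 in EpiC cultures (SD, n = 3 each), a log2 difference of 10.80 (SE 0.18). Krt17 stood at 2344 ± 174 against 1.45 ± 0.853 FPKM and Krt14 at 6551 ± 2545 against 153 ± 167. In the opposite direction, collagen genes were higher in EpiC cultures, with Col1a1 at 1027 ± 391 FPKM against 6.18 ± 0.759 in CRC (log2 −7.09, SE 0.30). The acute-phase gene Saa3 stood at 14280 ± 19880 against 9.996 ± 9.01 FPKM, with 37240 in EpiC culture 3. With limma, 2741 of 11837 genes were called, of which 1352 rose and 1389 fell in CRC relative to EpiC.

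**Figure D1:**
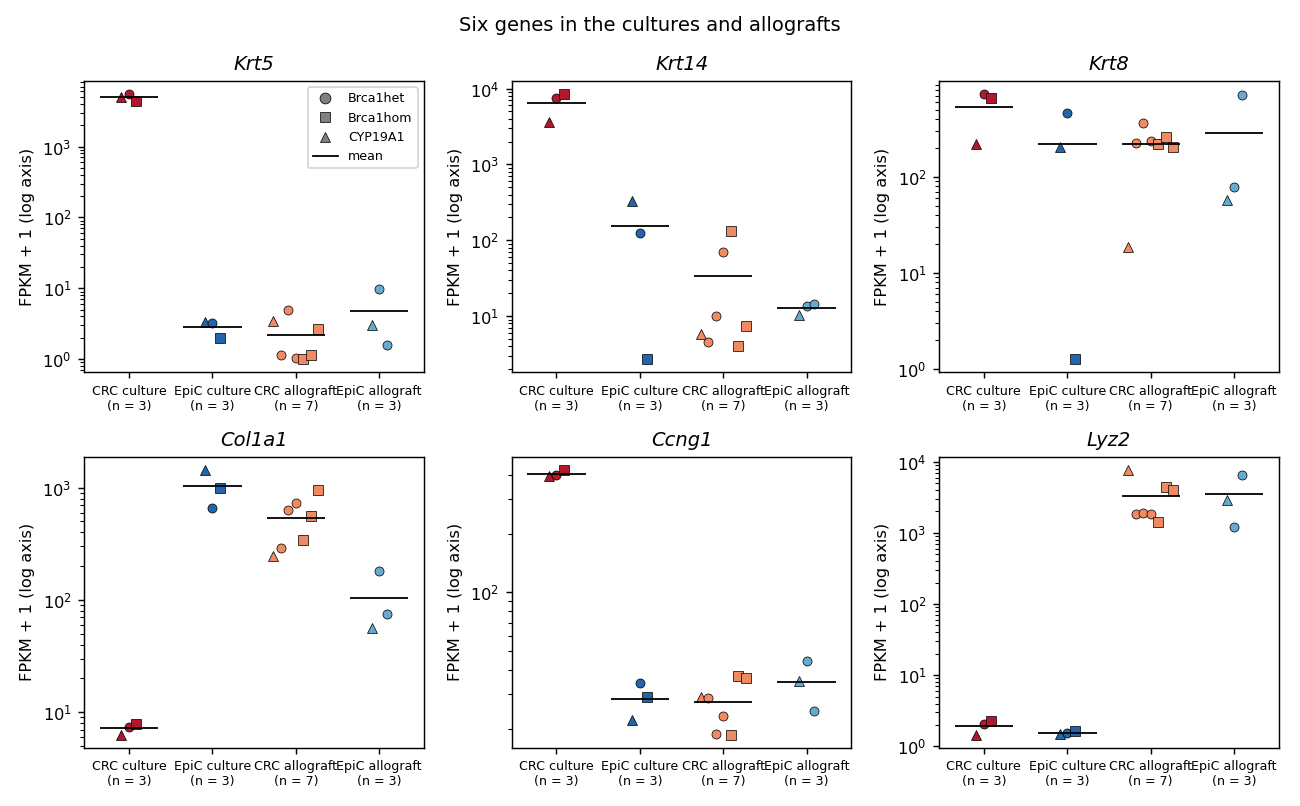
FPKM + 1 on a log axis for 6 genes in the cultures and allografts, 1 point per library, with marker shapes for genotype and a line at the mean of each group (n below each group). Krt5 lies between 4450 and 5460 FPKM in the 3 CRC cultures and at or below 8.68 in every other library drawn, while Lyz2 is high in allografts alone.

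Of 22 tested genes of squamous differentiation, 17 rose in CRC cultures and 0 fell (20 rose when adjusted over the list alone). Krtdap, a keratinocyte differentiation gene, stood at 860 ± 343 FPKM against 0.199 ± 0.175, Krt6a at 1160 ± 387 against 2.64 ± 3.39, and Krt6b at 241 ± 113 against 0.14 ± 0.102. The list was called by limma's camera (adjusted p = 1.02e-10), but not with an estimated correlation (adjusted p = 0.159). Among 17 basal and myoepithelial genes 10 rose (13 rose and 1 fell adjusted over the list alone; adjusted p = 4.17e-05, and 0.849 with an estimated correlation). Lgals7, a galectin of stratified epithelia, stood at 587 ± 375 FPKM against 0.502 ± 0.324, and the defensin gene Defb14 at 398 ± 222 FPKM against 3 EpiC libraries listed at 0. Of 21 luminal genes 3 rose and 0 fell (3 adjusted over the list alone), namely Prom1 (8.50 ± 5.34 against 0.0834 ± 0.0321 FPKM), Aldh1a3 and Grhl2. The luminal list was called (adjusted p = 0.046), but not with an estimated correlation (adjusted p = 0.914) nor without EpiC culture 3 (adjusted p = 0.374).

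Fibroblast and collagen genes fell in CRC cultures in 18 of 20 cases (20 adjusted over the list alone; camera adjusted p = 2.13e-13, and 0.159 with an estimated correlation). Besides Col1a1, Col1a2 stood at 10.3 ± 5.27 FPKM in CRC and 1319 ± 221 in EpiC cultures, and Col3a1 at 4.54 ± 2.16 and 657 ± 355. Genes of mesenchymal transition fell in 17 of 20 cases (18 adjusted over the list alone; adjusted p = 6.03e-11, and 0.159 with an estimated correlation). Prrx1, a mesenchymal transcription factor gene, stood at 2.17 ± 0.888 against 127 ± 10.7 FPKM, and Loxl2, which encodes a collagen crosslinking enzyme, at 0.164 ± 0.144 against 49.5 ± 25.1. The matrix genes Bgn (6.27 ± 1.97 against 1693 ± 399 FPKM) and Thbs2 (1.95 ± 0.703 against 529 ± 338) were among the largest decreases. Of 19 inflammatory cytokine genes 11 fell, both over all genes and adjusted over the list alone (adjusted p = 0.000257, and 0.914 with an estimated correlation). The monocyte attractants Ccl2 (9.12 ± 5.86 against 756 ± 232 FPKM) and Ccl7 and the cytokine gene Il6 (0.896 ± 0.24 against 102 ± 74.1) were among them.

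Among 23 p53 target genes 13 rose and 2 fell in CRC cultures, with the same counts adjusted over the list alone (camera adjusted p = 0.00014, and 0.284 with an estimated correlation). Ccng1 (cyclin G1) stood at 405 ± 15.8 against 27.5 ± 6.03 FPKM, a log2 difference of 3.85 (SE 0.19), and the pro-apoptotic gene Pmaip1 at 52.5 ± 21.5 against 2.26 ± 1.66. Perp, which encodes a desmosome component also found in stratified epithelia, stood at 1945 ± 73.6 against 60.8 ± 56.3. Trp53 itself was not called (19.8 ± 6.73 against 11.9 ± 15.2 FPKM, adjusted p = 0.149). Cholesterol synthesis genes rose in 5 of 24 cases (14 adjusted over the list alone; adjusted p = 0.00014, and 0.914 with an estimated correlation), for example Hmgcs1 at 150 ± 33.8 against 36.9 ± 19.1 FPKM. Mitosis genes rose in 5 of 22 cases (5 adjusted over the list alone; adjusted p = 0.00626, and 0.849 with an estimated correlation), with Ccnb1 at 51.2 ± 9.81 against 25.8 ± 4.86 FPKM.

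Lists that were not called still held called members. Of 9 Notch genes 5 rose and 1 fell, both over all genes and adjusted over the list alone, with the Notch target Hes1 at 86.1 ± 7.45 against 10.6 ± 9.14 FPKM. On the milk protein list 1 of 10 genes rose and 2 fell, with the same counts adjusted over the list alone; Spp1 (osteopontin) stood at 198 ± 149 against 7234 ± 1865 FPKM. Gsta4, a glutathione transferase gene on the list of NRF2 targets, stood at 1349 ± 263 against 20.5 ± 16.2 FPKM, and Vegfa at 13.9 ± 1.06 against 97.7 ± 34.6. The RANK ligand gene Tnfsf11 stood at 0.335 ± 0.274 against 21.5 ± 16.3 FPKM. The count of called genes was 159 without CRC culture 2, 168 without EpiC culture 2, 565 without CRC culture 1, 671 without EpiC culture 1 and 1658 without a filter. Of the 64 called genes taken by the rule for named genes, 18 kept their call whichever library was left out, among them Krt5, Krt17, Col1a1, Saa3 and Ccng1, while Krt14 (largest adjusted p = 0.155), Perp (0.124) and Hmgcs1 (0.116) were among those that lost it.

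**Figure D2:**
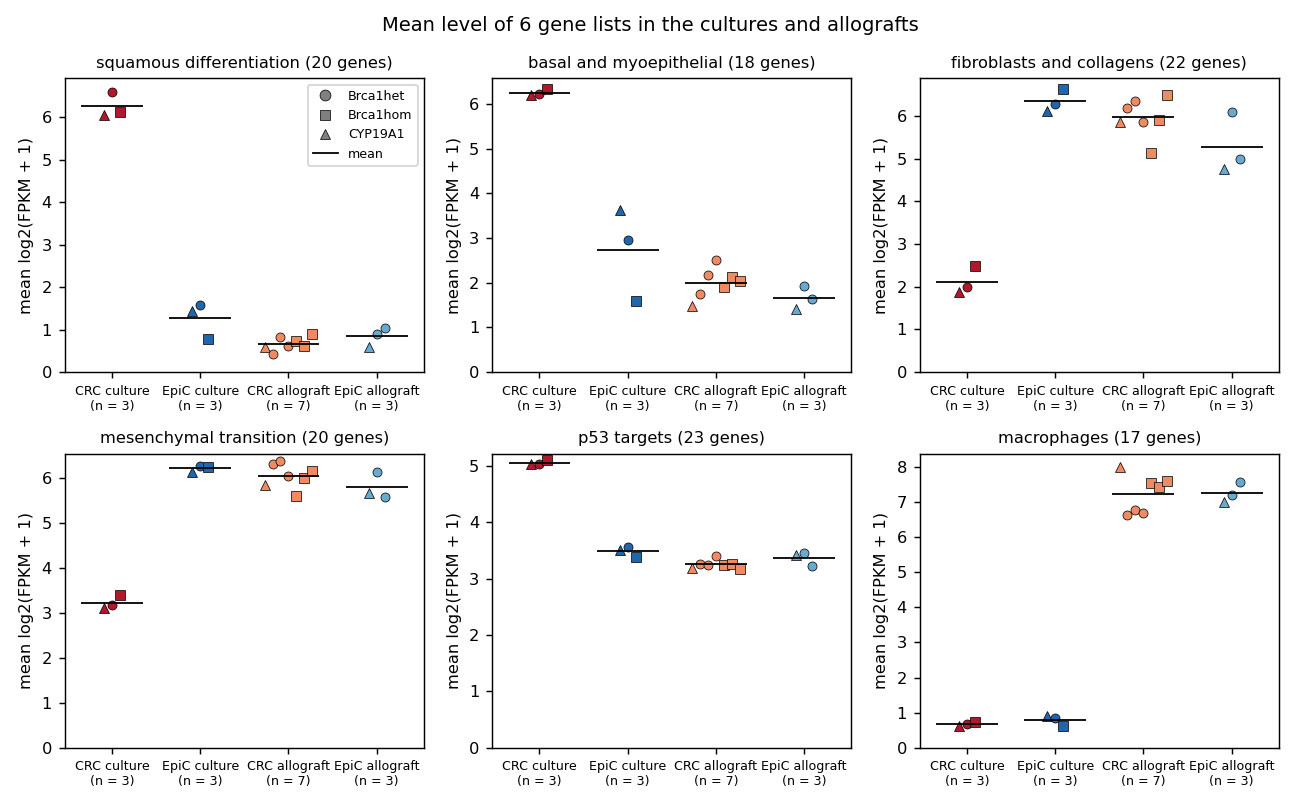
Mean log2(FPKM + 1) of 6 gene lists in each culture and allograft, 1 point per library, with marker shapes for genotype and a line at the mean of each group (n below each group). The squamous list lies at 6.05 to 6.61 in CRC cultures and at or below 1.58 in every other library drawn, and the macrophage list lies at 6.62 to 7.99 in allografts and at or below 0.895 in cultures.

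In allografts few genes were called between the media of origin, which does not show that few differed. Of the simulated genes changed 2-fold, this test called 12%. Brca1hom had only CRC allografts, so with genotype in the model the medium effect came from Brca1het (3 against 2 libraries) and CYP19A1 (1 against 1). The means given cover all 7 CRC allografts and so mix genotype with medium. Tmsb15a, a thymosin beta gene, was the only gene called among 11999: it was listed at 0 in 5 of the 7 CRC allografts, stood at 1.00 and 0.55 FPKM in CRC allografts 1 and 2, and at 6.30 ± 1.96 FPKM in EpiC allografts (SD, n = 3; limma log2 −2.86, SE 0.30, adjusted p = 0.033). At an unadjusted p under 0.05 there were 1011 genes. Some of the genes with the next smallest p-values, with an adjusted p of 0.0892 each, are given as values. Olfml2b stood at 60.2 ± 28.0 FPKM in CRC (n = 7) and 11.1 ± 9.16 in EpiC allografts, and Fkbp11 at 55.2 ± 18.7 and 15.8 ± 0.971. Socs2, a feedback inhibitor of cytokine signalling, stood at 4.99 ± 1.45 and 17.3 ± 3.10, and the granzyme gene Gzmc at 10.2 ± 12.1 and 71.1 ± 7.63.

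Several lists, among them markers of other cell types, were called between the media of origin in allografts, without any member called over all genes. None of these 9 calls held with an estimated correlation (adjusted p = 0.349 to 0.523). The skeletal muscle list (13 genes, median log2 1.75, camera adjusted p = 4.52e-07), the endothelial list (14 genes, 0.69, 0.000681) and the fibroblast list (22 genes, 0.44, 0.00309) were shifted towards CRC. The lymphocyte list (7 genes, −0.97, 3.76e-06), the luminal list (13 genes, −0.91, 0.000681), antigen presentation (18 genes, −0.70, 0.0031) and the interferon response (27 genes, −0.42, 0.00122) were shifted towards EpiC. Mitosis (22 genes, 0.37, 0.00256) and DNA replication (23 genes, 0.41, 0.00135) were shifted towards CRC. CRC allograft 1 stood apart from the other CRC allografts, with mean log2(FPKM + 1) levels of 2.54 on the lymphocyte list (0.922 to 1.49 in the others) and 2.83 on the luminal list (0.83 to 1.63). Adjusted over the list alone, 3 luminal and 3 lymphocyte genes were lower and 2 fibroblast genes higher in CRC allografts, and 0 members of the other 6 lists passed. The call of Tmsb15a ended without CRC allograft 10B (adjusted p = 0.191), 10C (0.225), 11C (0.0874) or 2 (0.0553) and without EpiC allograft 4C (0.061) or 5A (0.181). The count was 0 without 10B, 10C or 5A, 3 without 4C, 5 without 12, 9 without 6C or 7B, 47 without CRC allograft 1 and 17 among Brca1het allografts alone.

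Allografts held RNA of macrophage and endothelial markers that were near 0 in the cultures, and lower levels of many squamous, basal and luminal genes. Lyz2, the lysozyme gene of macrophages, stood at 3378 ± 2262 FPKM in allografts (SD, n = 10) and 0.752 ± 0.346 in cultures (n = 6), a log2 difference of 10.72 (SE 0.40). The complement gene C1qa stood at 1056 ± 523 against 0.226 ± 0.125 FPKM, and the protease gene Ctss at 863 ± 437 against 0.157 ± 0.0957. Lcn2 (lipocalin 2) stood at 25.6 ± 47.0 FPKM in allografts and 1604 ± 1717 in cultures, and Trp63, which encodes the basal regulator p63, at 0.234 ± 0.287 against 28.9 ± 28.0. Over the 16 libraries limma called 4257 of 12325 genes, of which 2238 rose and 2019 fell in allografts. Each of the 10 allografts correlated more closely with the EpiC cultures (r across genes 0.773 to 0.827) than with the CRC cultures (0.686 to 0.717). Genes are not independent replicates. Collagen and mesenchymal genes were higher in EpiC than in CRC cultures, and host tissue can bring such RNA to an allograft. The correlation therefore cannot tell a change of the grafted cells from RNA of host cells.

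All 17 tested macrophage genes rose in allografts, also adjusted over the list alone, and this list kept its call with an estimated correlation (camera adjusted p = 1.49e-25, and 0.0218 with an estimated correlation). The other calls were lost with an estimated correlation (adjusted p = 0.249 to 0.686). Endothelial genes rose in 13 of 14 cases (13 adjusted over the list alone; camera adjusted p = 6.56e-10), with Pecam1 at 29.0 ± 13.8 against 0.243 ± 0.192 FPKM. Lymphocyte genes rose in 4 of 5 cases (5 adjusted over the list alone; 0.00317), with Cd4 at 3.61 ± 2.31 against 0.00561 ± 0.00883 FPKM. Antigen presentation genes rose in 8 of 17 cases (9 adjusted over the list alone; 0.000447), with Cd74 at 908 ± 1213 against 2.999 ± 2.14 FPKM. The fibroblast (12 of 22 rose and 1 fell; 13 and 1 adjusted over the list alone; 0.00242) and mesenchymal lists (11 of 20 rose and 1 fell; 13 and 1; 0.000683) were shifted up. This rise was seen for CRC alone. The fibroblast mean log2(FPKM + 1) was 1.86 to 2.48 in CRC cultures and 5.13 to 6.49 in CRC allografts, but 6.12 to 6.64 and 4.76 to 6.08 for EpiC. The mesenchymal mean was 3.11 to 3.41 and 5.60 to 6.37 for CRC, but 6.13 to 6.26 and 5.57 to 6.14 for EpiC. Zeb1, a repressor of epithelial genes, stood at 25.1 ± 6.77 against 4.76 ± 5.16 FPKM. Interferon response genes rose in 7 of 25 cases (7 adjusted over the list alone; 0.0327), a list call that was lost without EpiC culture 3 (adjusted p = 0.113).

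Squamous genes fell in allografts in 18 of 20 cases (19 adjusted over the list alone; camera adjusted p = 1.5e-08, and 0.383 with an estimated correlation), with Sbsn (suprabasin) at 1.40 ± 0.761 against 179 ± 157 FPKM. Basal genes fell in 12 of 18 cases and 1 rose (15 and 1 adjusted over the list alone, camera adjusted p = 8.1e-06, and 0.249 with an estimated correlation). Krt5 reached at most 4.02 FPKM in CRC allografts (n = 7) and 8.68 in EpiC allografts (n = 3). It stood at 4450 to 5460 FPKM in CRC cultures but at 1 to 2.32 in EpiC cultures, so it fell for CRC alone. Both list falls were larger for CRC. The squamous mean log2(FPKM + 1) was 6.05 to 6.61 in CRC cultures and 0.435 to 0.903 in CRC allografts. For EpiC it was 0.768 to 1.58 and 0.593 to 1.03. The basal mean was 6.195 to 6.33 and 1.49 to 2.51 for CRC, but 1.60 to 3.63 and 1.42 to 1.93 for EpiC. Luminal genes fell in 13 of 20 cases (13 adjusted over the list alone; 8.19e-06), with Epcam at 4.03 ± 7.68 against 254 ± 145 FPKM. The lists that fell also included milk proteins (7 of 10 genes), cholesterol synthesis (14 of 23), glycolysis and hypoxia (12 of 22), p53 targets (9 of 23, with 1 that rose), inflammatory cytokines (10 of 19, with 1 that rose), YAP targets (6 of 18) and oxidative phosphorylation (6 of 24). The unfolded protein and amino acid response fell in 7 of 22 cases. Adjusted over the list alone, these 8 lists held 7, 17, 13, 14, 11, 6, 6 and 7 falls in that order, with 1 rise among p53 targets and 2 among cytokines, and their camera adjusted p-values lay between 5.17e-07 and 0.0241. Examples were Hmgcs1 (21.0 ± 7.60 against 93.5 ± 66.7 FPKM), the glucose transporter gene Slc2a1 (48.7 ± 40.5 against 126 ± 45.9), Trp53inp1 (3.23 ± 1.93 against 26.5 ± 21.8) and the neutrophil attractant Cxcl1 (11.96 ± 14.6 against 414 ± 399). Erbb2 stood at 5.94 ± 4.05 against 13.6 ± 4.35 FPKM (adjusted p = 0.0318). The fall of the p53 list was seen mainly for CRC, where its mean log2(FPKM + 1) was 5.02 to 5.11 in cultures and 3.17 to 3.40 in allografts. For EpiC the mean was 3.385 to 3.56 in cultures and 3.23 to 3.45 in allografts. The count of called genes was 935 with Brca1het libraries alone, and 70 of the 83 called genes taken by the rule kept their call whichever library was left out.

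The medium effect was then compared between allografts and cultures through the interaction of medium and state, for which limma called 1506 of 12325 genes, 783 with a more positive and 723 with a more negative CRC minus EpiC difference in allografts. For Krt5 the difference between the media was 10.80 log2 units in cultures, and it was lower by 11.58 units (SE 0.89) in allografts. Krt17 was lower by 10.35 (SE 0.53) and Krtdap by 9.69 (SE 0.97). In the other direction Col1a1 was higher by 9.35 (SE 0.69), and Bgn by 9.38 (SE 0.85). Col1a1 stood at 532 ± 257 FPKM in CRC allografts (n = 7) and 103 ± 67.3 in EpiC allografts (n = 3), a difference that was not called within allografts (adjusted p = 0.271).

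Squamous genes were lower in this interaction in 16 of 20 cases (19 adjusted over the list alone; camera adjusted p = 2.57e-22, and 0.000325 with an estimated correlation). Mesenchymal genes were higher in 16 of 20 cases (18 adjusted over the list alone; 5.56e-15, and 0.000564 with an estimated correlation), and fibroblast genes in 17 of 22 cases (17; 4.07e-17, and 0.0111 with an estimated correlation). Among 23 p53 targets 11 were lower and 1 higher (13 and 2 adjusted over the list alone; 7.86e-06, and 0.00318 with an estimated correlation). Cdkn1a, the gene of the cell cycle inhibitor p21, stood at 237 ± 13.8 FPKM in CRC cultures against 23.4 ± 11.5 in EpiC cultures, and at 25.5 ± 12.1 in CRC allografts against 46.9 ± 21.7 in EpiC allografts (interaction log2 −4.44, SE 0.56, limma adjusted p = 0.000177). The remaining 4 lists lost their call with an estimated correlation (adjusted p = 0.129 to 0.777): basal genes (8 of 18 lower; 12 lower and 2 higher adjusted over the list alone), luminal genes (4 of 20 lower; 5), cholesterol synthesis (4 of 23 lower; 10) and inflammatory cytokines (6 of 19 higher; 7). The count was 760 without CRC culture 3, 968 without CRC culture 2 and 1000 with a filter at 5 FPKM, and 37 of the 54 called genes taken by the rule kept their call whichever library was left out.

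Cultures of the primary cancers held little RNA of the macrophage, endothelial and fibroblast markers found in the cancers. In the table of the cancers, Lyz2 stood at 534 ± 239 FPKM in primary cancers, 0.919 ± 0.22 in CRC cultures and 0.368 ± 0.0309 in EpiC cultures (SD, n = 2 each). Cd74, the invariant chain of class II molecules, stood at 515 ± 221, 1.14 ± 0.512 and 3.35 ± 1.83 FPKM, and Ctss at 262 ± 45.7, 0.451 ± 0.194 and 0.175 ± 0.0663. Apoe stood at 958 ± 270, 3.30 ± 2.81 and 1.68 ± 0.0459 FPKM. Limma called 109 of 12266 genes between CRC cultures and cancers, 51 of which rose and 58 fell, and 83 between EpiC cultures and cancers, 31 of which rose and 52 fell. With the cancer as a block these counts were 58 and 29. The balance of directions depended on the setting: for CRC cultures 41 rose and 243 fell without a filter, 25 and 215 without cancer 1, 21 and 251 without cancer 2, 39 and 20 with a filter at 5 FPKM and 57 and 35 with a pseudocount of 0.1, and for EpiC cultures 29 and 255, 14 and 213, 18 and 266, 24 and 19 and 49 and 42 in that order.

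Macrophage genes fell in 9 of 17 cases in CRC cultures (16 adjusted over the list alone; camera adjusted p = 1.67e-32, and 0.0788 with an estimated correlation) and in 8 of 17 in EpiC cultures (15; 1.69e-38, and 0.0618). Endothelial genes fell in 2 of 9 and 1 of 9 cases (6 and 6 adjusted over the list alone; 2.22e-08 and 3.84e-13, and 0.0788 and 0.0559 with an estimated correlation). Emcn, an endothelial sialomucin gene, stood at 10.7 and 16.3 FPKM in cancers 1 and 2, was listed at 0 in the CRC culture of cancer 1 and in both EpiC cultures, and stood at 0.0654 in the CRC culture of cancer 2. Its calls were lost with the block (adjusted p = 0.0716 and 0.0769). Fibroblast genes fell in 1 of 20 and 2 of 20 cases (14 and 15 adjusted over the list alone; 2.06e-14 and 6.26e-24, and 0.0788 and 0.0559 with an estimated correlation). Postn (periostin) stood at 68.7 ± 42.9, 0.757 ± 0.318 and 1.34 ± 1.46 FPKM, with blocked adjusted p-values of 0.0749 and 0.0983, and Col1a1 at 52.3 ± 22.8 in cancers and 0.387 ± 0.129 in EpiC cultures, with a blocked adjusted p of 0.078. Antigen presentation genes fell in 4 of 17 cases in both (4 and 5 adjusted over the list alone; 2.14e-05 and 3.11e-09, and 0.55 and 0.351 with an estimated correlation).

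Further lists were called without any member called over all genes, and with an estimated correlation these calls had adjusted p-values of 0.109 to 0.661. Mitosis (21 genes; median log2 1.08 in CRC and 1.67 in EpiC cultures), DNA replication (23 genes; 0.79 and 0.96), homologous recombination repair (18 genes; 0.49 and 1.06), cholesterol synthesis (21 genes; 0.91 and 1.07) and oxidative phosphorylation (24 genes; 1.08 and 0.53) were shifted up in both. In CRC cultures some of these shifts lay mostly in 1 cancer. The mitosis mean log2(FPKM + 1) was 5.976 against 4.025 in cancer 1, but 4.959 against 4.833 in cancer 2. The repair mean was 2.793 against 1.776, but 1.938 against 1.898 in cancer 2. Oxidative phosphorylation moved from 7.252 to 7.519 with cancer 1 and from 6.844 to 8.579 with cancer 2. Milk proteins (13 genes; −1.78 and −2.90) were shifted down, but in cancer 1 alone: their mean log2(FPKM + 1) was 7.56 in cancer 1 against 3.57 in its CRC and 2.07 in its EpiC culture, and 2.49 in cancer 2 against 2.76 and 2.79. Squamous genes were shifted up in CRC cultures (14 genes; 1.94). In EpiC cultures luminal (23 genes; −0.36), mesenchymal (17 genes; −0.68) and glycolysis and hypoxia genes (22 genes; −0.52) were shifted down, and YAP targets (17 genes; 0.50) and the unfolded protein and amino acid response (22 genes; 0.06) up. Adjusted over the list alone, 2 mesenchymal genes fell, and 2 genes each of cholesterol synthesis and of the unfolded protein response rose, in EpiC cultures; 0 members of the others passed. In CRC cultures the squamous (adjusted p = 0.41) and milk protein (0.0954) calls were lost without the CRC culture of cancer 2, as was that of the unfolded protein response in EpiC cultures (0.0818).

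Most genes that rose in cultures of cancers lay on chromosome 4 of GRCm38.p6: 46 of 51 in CRC and 25 of 31 in EpiC cultures, against 5 of 58 and 5 of 52 of those that fell. Slc2a7, a sugar transporter gene, was listed at 0 in both cancers and at 368, 343, 329 and 173 FPKM in the CRC cultures of cancers 1 and 2 and the EpiC cultures of cancers 1 and 2. BC049635 was listed at 0 in both cancers and at 154, 148, 165 and 81.5 FPKM in the same order. Snord73a was listed at 0 in both cancers and at 204, 449, 554 and 288 FPKM. It is a small RNA gene, and FPKM is scaled to transcript length, so a few fragments may give such values. Tmem68 stood at 15.5 and 26.8 FPKM in the cancers and at 789 and 7383 in CRC cultures, with a blocked adjusted p of 0.0634. Without chromosome 4, 25 genes were called in CRC cultures (3 rose and 22 fell) and 33 in EpiC cultures (5 rose and 28 fell). Across the chromosome 4 genes each of the 4 cultures correlated at 0.573 to 0.675 with the mean of the cultures and allografts of the other, separately normalised table, against 0.778 or more on every other chromosome, while the cancers reached 0.853 and 0.89. None of the 17 called genes taken by the rule in either comparison kept its call whichever library was left out: the counts for CRC cultures were 240 and 272 without primary cancer 1 or 2, 44 without the CRC culture of cancer 2, and 0 and 25 without the EpiC culture of cancer 1 or 2. For EpiC cultures they were 227 and 284 without primary cancer 1 or 2, 51 and 37 without the CRC culture of cancer 1 or 2, and 0 and 7 without the EpiC culture of cancer 1 or 2.

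**Figure D3:**
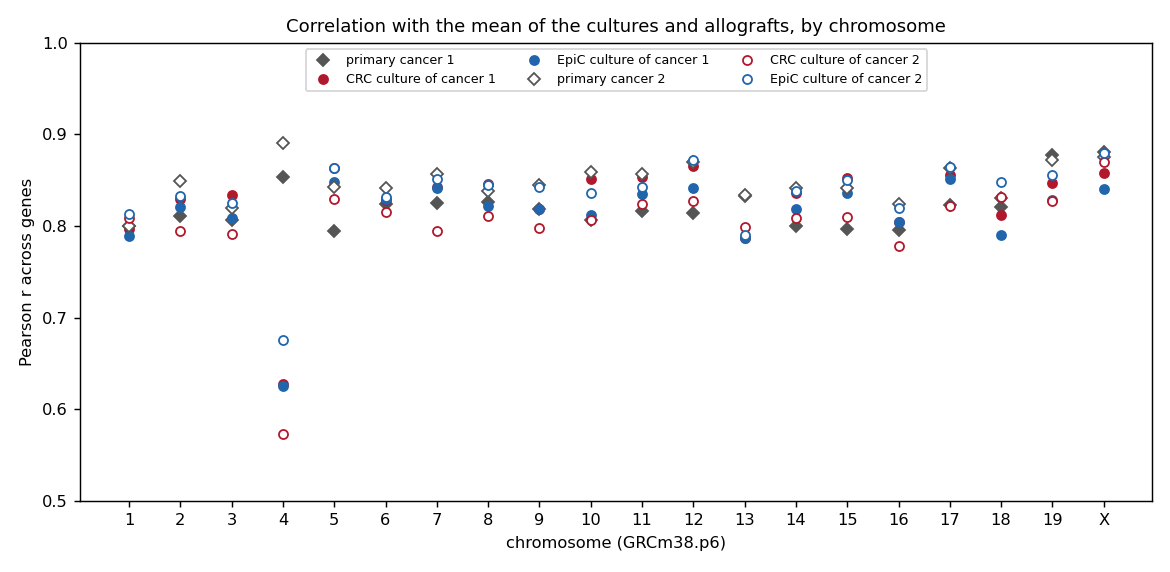
Pearson correlation, across the genes of each chromosome (GRCm38.p6), between a library of the cancer table and the mean of the 16 cultures and allografts on the log2(FPKM + 1) scale, 1 point per library and chromosome. On chromosome 4 the 4 cultures of cancers lie between 0.573 and 0.675, below their values on every other chromosome, and the primary cancers at 0.853 and 0.89 do not.

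Between the CRC and EpiC cultures of the cancers limma called 1 of 12266 genes, Mir186 (adjusted p = 0.0264). It was listed at 0 in both CRC cultures and at 200 and 312 FPKM in the EpiC cultures of cancers 1 and 2. Mir186 is a small RNA gene, so a few fragments may give such values. With the block the count was 0, and the adjusted p of Mir186 was 0.102. At an unadjusted p under 0.05 there were 200 genes. The smallest p-values in the other direction were those of the keratinocyte gene Dmkn, at 44.4 and 230 FPKM in CRC and 0.216 and 0.982 in EpiC cultures, and of Spink8, at 9.90 and 10.9 in CRC cultures and listed at 0 in both EpiC cultures (adjusted p = 0.489 each). Orm2, an acute-phase gene, stood at 90.8 and 180 against 0.259 and 6.24 FPKM. The squamous list was shifted towards CRC (14 genes, median log2 2.19, camera adjusted p = 5.53e-12), a call that was lost with an estimated correlation (adjusted p = 0.553) and without the CRC culture of cancer 2 (adjusted p = 0.259). It had mean log2(FPKM + 1) levels of 2.90 and 5.35 in CRC and 1.82 and 1.87 in EpiC cultures. Krt5, outside the rule and chosen after its values were seen, stood at 24.0 and 917 FPKM in CRC and 0.198 and 0.193 in EpiC cultures.

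Basal (16 genes, 0.48), mesenchymal (17 genes, 0.45), fibroblast (20 genes, 0.16), glycolysis and hypoxia (22 genes, 0.55) and oxidative phosphorylation lists (24 genes, 0.65) were also shifted towards CRC, and homologous recombination repair (18 genes, −0.43), YAP targets (17 genes, −0.77) and EGFR ligands and MAPK feedback (22 genes, −0.60) towards EpiC cultures of cancers. Adjusted over the list alone, 1 squamous gene and 0 members of the other lists passed, and none of the 9 list calls held with an estimated correlation (adjusted p = 0.553 to 0.724). Without the CRC culture of cancer 2 none of these 9 lists was called (adjusted p = 0.259 to 0.76), with a turn in direction for oxidative phosphorylation (adjusted p = 0.73). The count of genes was then 0, as it was without primary cancer 1 or the EpiC culture of cancer 1, and it was 12 without the CRC culture of cancer 1 and 4 without the EpiC culture of cancer 2. Of 2353 genes called between the media in the other cultures and tested here, 1184 (50.3%) had the same sign in cultures of cancers, and over 10882 genes the log2 differences of the separately normalised tables correlated at 0.1 (Pearson) and 0.00912 (Spearman) across genes, which are not independent replicates.

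No single gene was called between genotypes. Between Brca1hom and Brca1het CRC allografts (n = 3 each) limma called 0 of 11928 genes, with 1246 at an unadjusted p under 0.05. Genes with the smallest p-values had an adjusted p of 0.198: Sox2, a stem cell transcription factor gene, stood at 0.476 ± 0.642 FPKM in Brca1hom and 14.2 ± 3.34 in Brca1het, Hoxb7 at 11.3 ± 3.78 and 1.68 ± 0.543, Ltbp2 at 56.0 ± 7.27 and 17.1 ± 4.35, and the mesenchymal cadherin gene Cdh11 at 2.62 ± 2.999 and 48.6 ± 6.57. The macrophage list was shifted towards Brca1hom (17 genes, median log2 0.89, camera adjusted p = 2.62e-10, and 0.103 with an estimated correlation), with 0 members called over all genes and 11 higher adjusted over the list alone. Antigen presentation was shifted in the same direction (17 genes, 0.90, 1.32e-08, and 0.113 with an estimated correlation; 8 higher adjusted over the list alone). Endothelium (14 genes, −0.78), mitosis (22 genes, −0.35) and DNA replication (23 genes, −0.29) were shifted down, and the interferon response (26 genes, 0.21) and glycolysis and hypoxia (22 genes, 0.26) up, with 0 members past the test and adjusted p-values of 0.78 to 0.93 with an estimated correlation. The count of genes was 26 without CRC allograft 1 and 1 without CRC allograft 11C.

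Among cultures, 0 of 11837 genes were called by limma between Brca1hom and Brca1het (n = 2 each; 371 at an unadjusted p under 0.05). Of the lists 12 were called, none with an estimated correlation (adjusted p = 0.59 to 0.762), and 0 members passed adjusted over the list alone. Mitosis (22 genes, median log2 −0.60), DNA replication (23 genes, −0.29), homologous recombination repair (19 genes, −0.21), luminal (21 genes, −1.82), squamous (22 genes, −0.58), cholesterol synthesis (24 genes, −0.65), glycolysis and hypoxia (22 genes, −0.32), actin and SRF targets (18 genes, −0.29) and EGFR ligands and MAPK feedback (21 genes, −0.43) were shifted down in Brca1hom. Milk proteins (10 genes, 1.01), fibroblasts (20 genes, 0.50) and skeletal muscle (11 genes, 0.96) were shifted up. EpiC culture 3, where Krt8, Krt18, Epcam and Cdh1 stood below 1 FPKM, is 1 of the 2 Brca1hom cultures. Without it the luminal (adjusted p = 0.81), cholesterol (0.475), actin (0.0716) and EGFR (0.475) lists turned in direction and were not called, and without CRC culture 3 the count of genes was 204. Between CYP19A1 and Brca1het cultures 0 genes were called by limma (405 at an unadjusted p under 0.05). Mitosis (22 genes, 0.22) and antigen presentation (16 genes, 0.50) were shifted up, and DNA replication (23 genes, −0.40), the interferon response (24 genes, −0.36) and cholesterol synthesis (24 genes, −0.45) down. Only antigen presentation had members past the test adjusted over the list alone, with 2 higher, and all 5 calls had an adjusted p of 0.996 with an estimated correlation. Without EpiC culture 3 the number of lists called was 8. Clu (clusterin) stood at 28.5 ± 29.0 FPKM in CYP19A1 and 164 ± 154 in Brca1het cultures (adjusted p = 0.688), and the proteasome gene Psmb9 at 13.2 ± 0.634 and 4.20 ± 0.459 (adjusted p = 0.991).

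In allografts, 0 of 11999 genes were called by limma between CYP19A1 (n = 2) and Brca1het (n = 5), with 1158 at an unadjusted p under 0.05. Enpp1, a pyrophosphatase gene, stood at 49.6 ± 11.9 and 9.59 ± 2.26 FPKM, and Wisp2 at 1.90 ± 0.803 and 34.5 ± 27.4 (adjusted p = 0.0803 each). Skeletal muscle (13 genes, median log2 −1.60), endothelium (14 genes, −0.42), Notch signalling (11 genes, −0.70) and actin and SRF targets (18 genes, −0.54) were shifted down in CYP19A1, and macrophages (17 genes, 0.50) up. Adjusted over the list alone, 3 macrophage genes were higher and 1 Notch gene was higher and 2 lower, and 0 of the other lists passed; with an estimated correlation all 5 calls were lost (adjusted p = 0.665 to 0.833). The count was 3 without CRC allograft 6C, 6 without EpiC allograft 7B and 4 without EpiC allograft 4C, 1 with a pseudocount of 0.1 or without a filter, and 2 with a filter at 5 FPKM.

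Single allografts stood apart in runs of neighbouring genes, which were chosen after their values were seen. Met, the gene of the hepatocyte growth factor receptor on chromosome 6 (GRCm38.p6), stood at 443, 310, 765 and 637 FPKM in CRC allografts 10B, 10C, 2 and 12 and at 687 in EpiC allograft 5A, against 24.3 to 139 in the other allografts and 8.39 to 54.7 in the cultures. Its neighbours Tes, Cav2 and Cav1 were high in the same 4 CRC allografts, with Tes at 1540 to 3154 FPKM against 17.8 to 179 in the other allografts. In EpiC allograft 5A only Met, Capza2 (1641 FPKM) and St7 (173) were high and Cav1 stood at 61.2, while in CRC allograft 2 Capza2 stood at 137. Yap1, the gene of a Hippo pathway coactivator on chromosome 9, stood at 1075 FPKM in CRC allograft 11C and 261 in CRC allograft 1, against 21.0 to 52.5 in the other allografts, together with the apoptosis inhibitor genes Birc2 (203 and 90.5) and Birc3 (226 and 81.4).

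**Figure D4:**
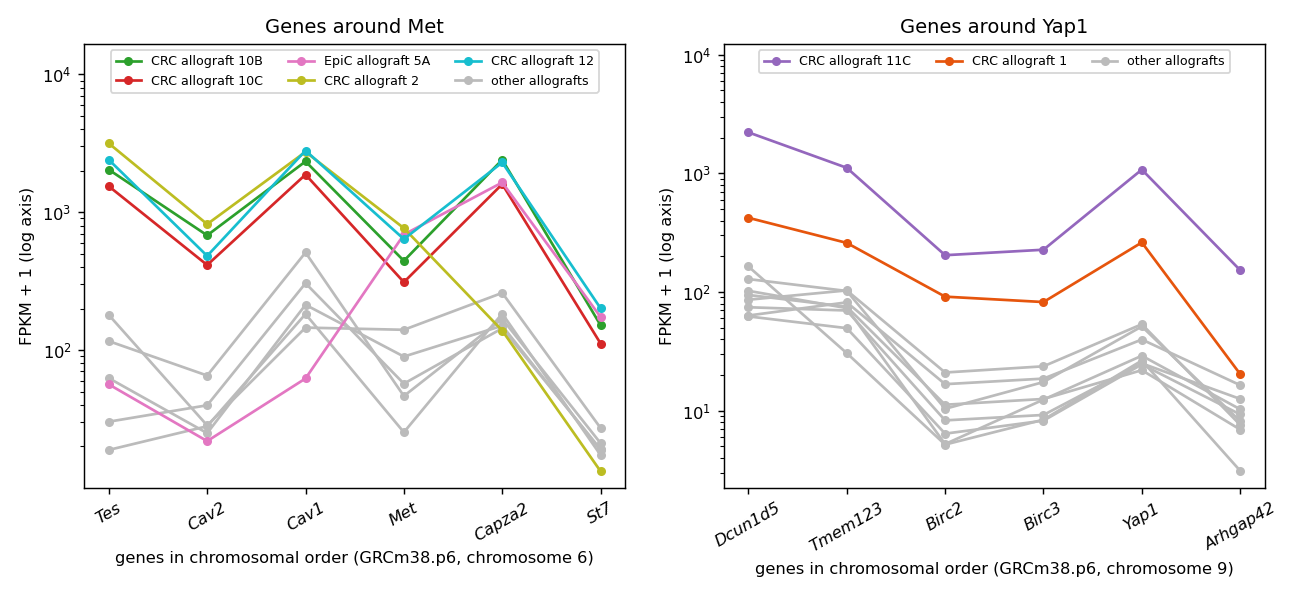
FPKM + 1 on a log axis for 6 genes around Met (chromosome 6) and 6 around Yap1 (chromosome 9, where genes lying between those drawn are left out), in the gene order of GRCm38.p6, 1 line per allograft with the raised ones coloured. Tes stands at 1540 to 3154 FPKM in 4 CRC allografts and at 17.8 to 179 in the others, and Yap1 at 1075 and 261 in CRC allografts 11C and 1 and at 21.0 to 52.5 in the others.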

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

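The splits of the samples were planned, as were the rules that pick out libraries and differences between groups; the tests on keratins, Epcam and Cdh1 and on the rescaled lists were chosen after the result was seen. The medium effect differed between allografts and cultures in 1506 genes by the interaction test of limma. Of 29 lists tested, 8 were called in that interaction, with camera adjusted p-values of 2.566e-22 for squamous, 4.069e-17 for fibroblast, 5.563e-15 for mesenchymal and 7.255e-06 for basal genes, 7.863e-06 for p53 targets, 0.0001025 for cholesterol synthesis, 0.001045 for inflammatory cytokines and 0.001524 for luminal genes. With an estimated correlation the basal, cholesterol, cytokine and luminal calls were lost (adjusted p = 0.129 to 0.777) and the other 4 held. Redrawing the medium within cultures and within allografts, without regard to genotype, gave as many genes in 4 of 100 splits, the real one included. This share is under 0.05, but by a thin margin for 100 splits. The highest other split called 1782 genes, more than the real one. A redraw could keep or exactly reverse the medium grouping of the cultures, and so still hold the real difference between them. Which splits did so was not recorded. The share is therefore not a rate for chance alone, and these splits cannot decide whether chance gave the count.

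Basal keratin and squamous genes were abundant in CRC cultures and far lower in CRC allografts. Between CRC cultures and CRC allografts Krt5 changed by −11.4 log2 units, Krt14 by −8.85 and Krt17 by −10.5, against −1.47 for Krt8 (SE 0.77), −2.90 for Krt18, −6.53 for Epcam and −6.22 for Cdh1. Host cells dilute all RNA of the grafted cells alike, but the average of the basal keratins lay below that of Krt8 and Krt18 by 8.07 (SE 0.62) and below that of Epcam and Cdh1 by 3.88 (SE 0.47); dilution cannot be told apart, because host epithelium also makes these genes, Epcam and Cdh1 fell close to the 1 FPKM added, and the conditions of this test were changed after the first value was seen. Rescaling by median ratios left both lists called between allografts and cultures, with a larger adjusted p of 1.164e-05, but with an estimated correlation both calls were lost (adjusted p = 0.383 for squamous and 0.249 for basal genes). Dilution, a change of state of the cells outside the medium and outgrowth of a few cells remain candidate explanations, and no biological explanation was tested.

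Among the 7 CRC allografts, 8 of 59 measures tested had a single library far from the others, by Dixon's ratio of the gap to the range. The bound was its 95% critical value, which chance exceeds in about 1 in 20 measures chosen without regard to these libraries. Insl6 and L3hypdh were taken for small p-values between CYP19A1 and Brca1het allografts, and Socs2 and Snora15 for those between the media. CRC allograft 6C is the only CYP19A1 library here, so that rate does not hold for these genes. CRC allograft 1 stood high in the mean log2(FPKM + 1) of luminal genes (2.83 against 0.83 to 1.63), milk proteins (3.12 against 1.57 to 2.06) and lymphocyte genes (2.54 against 0.922 to 1.49). CRC allograft 6C stood high in Insl6 (47.7 FPKM against 7.75 to 13.9) and L3hypdh (13.2 against 3.06 to 5.65) and low in Socs2 (2.04 against 4.29 to 6.42). Snora15 was listed at 0 in CRC allograft 2 against 42.4 to 493 FPKM, and p53 targets averaged 3.4 in CRC allograft 11C against 3.17 to 3.26. Snora15 is a small RNA gene, and FPKM is scaled to transcript length, so a few fragments may give values such as 42.4 FPKM.

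Other splits were also counted for the remaining comparisons of at least 3 libraries a side. For cultures by medium, 1 of 10 splits, the real one, called 2741 genes and the highest other called 0; 10 splits are too few for a share under 0.05. For allografts by medium, 25 of 100 splits called at least the real count of 1 gene, so chance was not excluded. The highest other called 439, which may reflect a structure of the samples. What that split followed was not tested. For allografts against cultures, 1 of 100 splits, the real one, called 4257 genes, and the highest other called 42, which excludes chance. For Brca1hom against Brca1het CRC allografts all 10 splits called 0 genes by limma (1246 at an unadjusted p under 0.05 in the real one), and they are too few for a share under 0.05.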

How the results depend on the processing

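The fits without chromosome 4, without small RNA genes, without genes listed at 0 and with a crossed block, and the lists without EpiC culture 3, without the CRC culture of cancer 2 or with the block, were chosen after the data were seen. Of 5166 checks on genes taken by the rule, 4621 left the gene called or not called as before, 514 lost the call and 31 gained it. Direction was checked only for genes called in the main fit, of which 0 turned. Of 589 checks on lists, 389 kept direction and call, 195 lost the call and 5 turned. Leaving out libraries and filtering change how many samples or genes are tested; beyond that the cause was not tested. Rescaling by median ratios changed no count by over 1.5 times and moved the share that rose by less than 10 points. Depth is unknown, so its limit on low genes could not be set.

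Without a filter, 1658 genes were called between media in cultures, 0 in allografts, 284 between CRC cultures and cancers, 284 between EpiC cultures and cancers, 0 between the media in cultures of cancers and 1 between CYP19A1 and Brca1het allografts. With a filter at 5 FPKM the counts were 0 in allografts, 59 and 43 for CRC and EpiC cultures against cancers, 5 between the media in cultures of cancers, 1000 for the interaction and 2 for CYP19A1 allografts. With a pseudocount of 0.1 they were 0 in allografts, 5 in cultures of cancers and 1 for CYP19A1 allografts. Allografts by medium gave 17 genes among Brca1het allografts alone and 0 with the mean of CRC allografts 10B and 10C as 1 sample, and allografts against cultures gave 935 with Brca1het libraries alone.

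With the cancer as a block, 58 genes were called between CRC cultures and cancers, 29 between EpiC cultures and cancers and 0 between the media, and the block called 16 lists for EpiC cultures against cancers and 10 between the media, against 15 and 9 without it, ending no list call; a block with the numbers of the cancers exchanged gave 69 for EpiC cultures. Without chromosome 4 the counts were 25 and 33 for CRC and EpiC cultures against cancers. Without genes listed at 0 in a library they were 46, 31 and 0, and without small RNA genes 0 between the media.

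With libraries left out in turn, the counts ranged from 159 to 2091 for media in cultures, 0 to 47 in allografts, 0 to 272 and 0 to 284 for CRC and EpiC cultures against cancers, 0 to 12 between the media in cultures of cancers, 2969 to 4706 for allografts against cultures and 760 to 2243 for the interaction. For genotypes they ranged from 0 to 26 in CRC allografts, 0 to 204 for Brca1hom and 0 to 0 for CYP19A1 in cultures, and 0 to 6 for CYP19A1 in allografts. Where a single library was left in a group, it is assumed to vary like the other groups.

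With an estimated correlation 1 list was called for allografts against cultures, 4 for the interaction and 0 for each other comparison. Fry called 5 lists for media in cultures, 0 in allografts, 3 and 5 for CRC and EpiC cultures against cancers, 0 between the media in cultures of cancers, 5 for the interaction, 2 for Brca1hom in CRC allografts and 0 for the other genotype comparisons. Without the CRC culture of cancer 2, 1 list was called between the media in cultures of cancers, and oxidative phosphorylation turned (adjusted p = 0.73). Without EpiC culture 3, 8 lists were called for CYP19A1 against Brca1het cultures, and 4 lists turned for Brca1hom against Brca1het cultures: luminal genes (adjusted p = 0.81), cholesterol synthesis (0.475), actin and SRF targets (0.0716) and EGFR ligands and MAPK feedback (0.475).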

Other observations

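The limma fits were planned, whereas the tests on a gain or loss of a chromosome, a shared response, library scaling and a shuffled gene order were chosen after the result was seen. The test on reads credited to neighbouring genes was written before its value was known but was prompted by pairs of neighbouring genes with similar values. Gzmc, Cdkn1a, Trp53, Ccng1 and Saa3 were taken by the rule for named genes; the others named here are outside it and were chosen after their values were seen. Granzyme genes, which encode proteases of cytotoxic lymphocytes, were higher in the 3 EpiC allografts than in 6 of the 7 CRC allografts. Gzmc stood at 65.7 to 79.8 FPKM against 2.57 to 11.5, Gzmd at 52.3 to 118 against 0.0336 to 8.89, Gzmf at 88.0 to 267 against 0.418 to 15.2 and Gzma at 13.3 to 53.8 against 0.618 to 4.21. CRC allograft 1 lay higher than the other CRC allografts, with Gzmc at 36.9, Gzmd at 29.7, Gzmf at 102 and Gzma at 31.0 FPKM. None of the 7 granzyme genes was called by limma between the media (adjusted p = 0.0892 to 0.375).

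The cell cycle inhibitor genes Cdkn1a and Cdkn2a went in opposite directions between the cultures. Cdkn1a (p21) stood at 237 ± 13.8 FPKM in CRC cultures and 23.4 ± 11.5 in EpiC cultures (SD, n = 3 each), and Cdkn2a, which encodes p16 and p19Arf, at 59.3 ± 44.2 and 459 ± 216 (limma adjusted p = 0.00979 and 0.00691). Trp53 stood at 2.09 and 4.24 FPKM in EpiC cultures 2 and 3 but at 29.4 in EpiC culture 1, where the p53 target Ccng1 was as low, at 21.3 against 33.3 and 28.1 FPKM. The mean log2(FPKM + 1) of 13 skeletal muscle genes ranged from 0.531 in EpiC allograft 7B to 5.41 in CRC allograft 10C.

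On chromosome 4, 12.6% of genes were at least 4-fold higher in the 4 cultures of cancers than in the cancers, against 0 to 1.3% on the 19 other chromosomes. Reads credited to the wrong neighbour would tie a gene's increase to its most abundant neighbour; that correlation was 0.114 across chromosome 4 genes (95% interval by Fisher's transformation 0.0454 to 0.182, with genes taken as independent), exceeded on 1 of the 19 others (−0.157 to 0.135), so that this explanation cannot be told apart. A gain or loss of the chromosome would move all its genes, but their median difference was −0.0716, within −0.226 to 0.358 on the others. A response shared with the 6 cultures of the other, separately normalised table would put most of the 47 genes that rose at 1 FPKM or more there, but 11 were, a share of 0.234 (exact 95% interval 0.123 to 0.38), which argues against it for the set as a whole and leaves those 11 genes open; the bound for this share was changed after it was seen. A difference in quantification limited to chromosome 4 in these 4 libraries remains a candidate explanation, since reads were not analysed here.

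The neighbouring genes around Met in 4 CRC allografts and around Yap1 in 2 were raised by medians of 2.29 to 4.1 log2 units over the median of the allografts; the 6 genes around Yap1 are not all consecutive, and in CRC allograft 1, with the 2.29, the highest window of 6 consecutive genes was 2.1. Library scaling moved the median of all genes in these allografts by at most 0.0224, far less. Single genes high by chance next to each other were tested by shuffling the gene order 100 times: in 10 of 10 allografts the highest window of 6 genes in genome order exceeded every shuffled one, and around Met 2.34 to 3.15 stood against at most 1.43, around Yap1 3.95 against 1.62 in CRC allograft 11C and, by a thin margin, 2.1 against 1.85 in CRC allograft 1. This argues only against single genes high by chance. It does not set these runs apart from other neighbouring genes that vary together. CRC allograft 6C, without a raised region, also exceeded its shuffles (1.6 against 1.25). The comparison within each library also replaced earlier versions. These were a version over all allografts, whose shuffles reached 2.68 in EpiC allograft 5A, then a version over the 6 with a raised region. A first version used shares of windows (at most 0.000707). Amplified DNA may underlie the runs around Met and Yap1, as a hypothesis; the highest windows of the EpiC allografts (2.94 to 3.83) lay in the mast cell protease and granzyme cluster, what raised those was not tested, and no DNA was analysed here and no biological explanation tested.

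Further values around these regions were seen in single libraries. In primary cancer 2, Met stood at 1818, Capza2 at 2860 and Tes at 2997 FPKM, against 13.3, 48.2 and 49.3 in its CRC culture and 68.2, 306 and 378 in its EpiC culture. In cancer 1 they stood at 19.1, 115 and 41.9 FPKM, against 157, 521 and 291 in its CRC culture and 24.7, 164 and 108 in its EpiC culture. In CRC allograft 2, the cell cycle kinase gene Cdk6 stood at 69.4 FPKM and its neighbours Gatad1 at 521 and Ankib1 at 127, against 1.27 to 6.52, 24.8 to 63.3 and 4.43 to 15.2 in the 15 other cultures and allografts. Saa3 stood at 2111 FPKM in EpiC allograft 7B and 1161 in CRC allograft 1, and at 17.5 to 48.4 in the other allografts.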
